A study of Homo sapiens with 16 samples.

How the data were processed

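The series holds 16 single-cell RNA libraries of human islets, 4 donors under each of 4 conditions for 96 h. The sample names carry treatment codes, which were read as DMSO, harmine, harmine with GLP1RA and harmine with LY364947 from the series' design text. The doses are those of the treatment protocol (10 µM, 5 nM and 10 µM) and were taken to hold in the combinations. The GLP-1 receptor agonist is not named in the labels. Libraries are called by group and replicate, which is the donor in the sample names.

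The deposited values are UMI counts per gene and barcode, as whole numbers, for 36601 genes and 253462 barcodes. Per the file headers, the authors made them with Cell Ranger, version 6.0.1 for donor 1, 7.0.0 for donors 2 and 4 and 6.1.0 for donor 3. Per the submitters' processing notes, the genome was GRCh38 and Seurat 4.0.3 was used, in a role that is not stated. Whether intronic reads were counted is not stated, and the default differs between these Cell Ranger versions. Each donor has all 4 conditions under 1 version, and values within versions 6 and 7 (2 donors each) are given beside pooled ones. No free RNA was removed from the deposited counts as far as stated, and none was removed here.

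Choices of tests, lists, markers, filters and alternatives were fixed before the data were examined, except where said. XIST, TSIX and Y-linked genes (113) were left out, which left 36488. Cells with at least 1000 UMIs, at least 500 genes and at most 25% mitochondrial UMIs were kept (189400). Scrublet in scanpy 1.11.5 scored doublets per library, and the top cells were removed at 0.8% per 1000 kept cells, 3.60% to 26.3% of a library, leaving 165724 cells. Total UMIs per library, in units of 1e6, were 114.5 to 157.1 for donor 1, 108.7 to 160.4 for donor 2, 49.4 to 83.0 for donor 3 and 90.9 to 131.1 for donor 4. The median UMIs per kept cell averaged 8118, 8119, 6079 and 4423 over the libraries of DMSO, harmine, GLP1RA and LY364947, and the median mitochondrial share 6.38%, 8.25%, 7.25% and 7.48%.

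For clustering, 2000 cells per library (32000) were drawn and reduced to 2000 variable genes and 30 principal components. Mitochondrial, ribosomal protein and cell-cycle list genes, and 1573 genes correlated above 0.1 with those lists, were left out, and genes were centred within each donor. A graph of 15 neighbours was clustered by Leiden (leidenalg 0.10.2) at resolution 0.6 into 23 clusters, and the remaining cells took the cluster of their neighbours. A cluster was named by the class with the highest mean log2 fold of its markers over other clusters (pseudocount 10 CPM), at least 1 and at least 0.5 above the next class, with at least 3 markers at 2-fold. Non-endocrine classes were tried first, at 2. This named 18 clusters in 12 classes and 119591 cells. The beta-like class is clusters 2, 4, 7, 12 and 14, alpha-like 0 and 10, ductal-like 6 and 22, and mesenchymal-like 3. Clusters 1, 5, 9, 13 and 20 stayed unnamed, with best scores for beta, alpha, beta, acinar and beta. They held 11.7%, 3.96%, 2.52%, 2.82% and 0.179% of cells after DMSO. After harmine these were 11.4%, 7.19%, 4.19%, 2.15% and 0.362%, with GLP1RA 14.8%, 8.05%, 4.15%, 1.62% and 0.444%, and with LY364947 9.86%, 5.92%, 3.67%, 0.949% and 0.293%. When each cell was named by its own markers instead, 23213 cells (14.01%) lay within 0.1 of the limit between 2 classes.

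UMIs were summed per class and library (at least 20 cells). Each class was fitted in edgeR 4.0.16 (R 4.3.3) over all 16 libraries by quasi-likelihood, with TMM scaling, filterByExpr, no donor term and Benjamini-Hochberg adjustment at 0.05 over all genes of a class and contrast. CPM values are TMM-scaled. The 5 contrasts were each treatment against DMSO and both combinations against harmine, the latter in beta-like and alpha-like cells. The difference between alpha-like and beta-like responses was the interaction in a fit of both sums with the library as a block. Gene lists, 27 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it. Adjustment ran over the 27 lists per class and contrast. Members were counted over all genes and adjusted over the list alone. The p-values measure spread between donors, and donors contribute to every group, so that a fit without a donor term leaves donor differences in its error.

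The lists were G1/S, G2/M, cyclins with CDKs and activators, cell-cycle inhibitors, p53 targets, TGF-beta and SMAD targets, beta identity, alpha identity, other hormones, cAMP and CREB response, AHR targets, DYRK and CLK kinases with NFAT, ER stress, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, interferon, NF-kB and cytokines, immediate-early and heat shock, progenitor, oxidative stress, secretory granule, apoptosis, acinar, ductal, mesenchymal and endothelial, and immune genes. They share members, and the beta-like, alpha-like and acinar-like class markers are partly in the corresponding lists.

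Genes were named by a rule. It named 16 genes always (among them INS, GCG, SST, PPY, MKI67, TOP2A, CDK1, CCND1, CCND2, CDKN1A, CDKN1C, MAFA, PDX1 and NKX6-1), and the 8 largest rises and falls per contrast against DMSO with an adjusted p under 0.05, a mean log2 CPM of at least 4 and the same sign in all 4 donors (5 each way elsewhere). It also named the 3 members with the smallest adjusted p in each list that passed. The text gives the values that matter most among these, and some of the genes are not reported here. List members printed without a value were named after their values were seen. Coordinates are from GENCODE 29.

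Shares of cells with an MKI67 or TOP2A UMI were taken after thinning each cell to 2000 UMIs, leaving out shallower cells, and classes as shares of all kept cells without doublets. Shares were compared by an exact permutation test of the difference in means (two-sided; smallest p 0.0286), in families of 9 and 36 tests. Alternatives were the donor as a block (for shares a sign-flip test, smallest p 0.125), DESeq2 1.42.0, RLE scaling, no filter on low counts, doublets kept, stricter cell filters (1000 genes, 15% mitochondrial), classes from each cell's own markers, an estimated list correlation, edgeR on cell counts, other thinning, and each library or donor left out. A wider naming of clusters (gap 0.25) was added later.

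The pairing of libraries by donor was checked on the sums after removing group means. All 24 same-donor pairs correlated above 0.1 in each of the 4 classes (medians 0.647, 0.647, 0.575 and 0.563), and all 16 libraries lay closest to their own donor. No library repeated another of its group (24 pairs). The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. They recovered 39 and 71 of them in beta-like sums, 36 and 79 in alpha-like, 15 and 80 in ductal-like, 16 and 78 in mesenchymal-like and 54 and 93 in the interaction, with 3, 7, 7, 0 and 13 false calls. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9.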

Results

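Human pancreatic islets, the clusters of hormone-secreting cells of the pancreas, were cultured for 96 h under 4 conditions and read by single-cell RNA sequencing in droplets, which counts unique molecular identifiers (UMIs) per gene and cell barcode. The conditions were the solvent DMSO, harmine at 10 µM, harmine with a GLP-1 receptor agonist (GLP1RA) at 5 nM, and harmine with LY364947 at 10 µM. Harmine inhibits the kinase DYRK1A, which restrains cell-cycle entry. GLP-1 receptor agonists raise cAMP in cells that carry the receptor, and LY364947 inhibits the TGF-beta type I receptor kinase. Islets of the same 4 donors went through every condition, so that each group held 4 libraries and the series held 16. Total counts ran from 49373790 to 160354861 UMIs per library. Between 4496 and 32855 cells per library passed the filters, with a median of 1925 to 15863.5 UMIs per cell.

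Classes from marker genes are called beta-like, alpha-like and so on, since no label gives a cell type. The beta-like class held 42943 cells (891 to 4660 per library), the alpha-like class 33168 (601 to 4541), the mesenchymal-like class 14676 (154 to 2018) and the ductal-like class 8684 (174 to 1133). UMIs were summed per class and library, which gave 6.45 to 50.05 M UMIs per library for beta-like cells, 5.54 to 40.2 M for alpha-like cells, 1.38 to 16.3 M for ductal-like cells and 2.07 to 50.4 M for mesenchymal-like cells, in units of 1e6. Differences are log2 fold changes between groups of 4 libraries, and levels are CPM (UMIs of a gene per 1e6 UMIs of the class) as mean ± SD over 4 libraries.

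Beta-like cells were first compared between harmine and DMSO. After harmine, 7 of 27 genes of beta cell identity and 7 of 58 G2/M genes stood higher than after DMSO, and the transcript of insulin was not detectably different. SLC2A2 (ENSG00000163581, chromosome 3, 170996348 to 171026750, minus strand, GRCh38), which encodes the glucose transporter GLUT2, rose from 16.4 ± 6.84 to 127 ± 19.9 CPM (log2 fold change 2.96, SE 0.26, adjusted p = 1.88e-05, n = 4). MAFA (ENSG00000182759, chromosome 8, 143419182 to 143430406, minus strand), an activator of the insulin gene, rose from 134 ± 53.9 to 334 ± 52.9 CPM (log2 fold change 1.32, SE 0.23, adjusted p = 0.00693). NKX6-1 and PDX1, both needed for beta cell identity, rose by 1.28 and 1.11 on the log2 scale (adjusted p = 0.00522 and 0.00973), and PCSK1, a convertase of proinsulin, by 1.24 (adjusted p = 0.00109). INS (ENSG00000254647, chromosome 11, 2159779 to 2161341, minus strand) had a log2 fold change of −0.20 (SE 0.48, adjusted p = 0.938).

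Among genes with the same sign in all 4 donors, GCNT4, a glycosyltransferase of mucin-type chains, rose as far as SLC2A2, from 11.8 ± 3.08 to 92.2 ± 30.5 CPM (log2 fold change 2.96, SE 0.32, adjusted p = 0.00015). The neurofilament gene NEFM (2.80), the thrombin receptor THBD (2.35), the co-repressor ZNF703 (2.08) and the diabetes-locus gene C2CD4A (2.05) also rose (adjusted p = 0.00361, 0.0023, 0.00103 and 0.00103). Genes of mitosis that passed were CENPF (2.87, adjusted p = 0.0186), NUSAP1 (2.59, adjusted p = 0.00683), TOP2A (2.46, adjusted p = 0.048), HMMR (2.44, adjusted p = 0.0136) and PRC1 (1.70, adjusted p = 0.00871). With doublets kept, CENPF (1.93), TOP2A (1.87) and PRC1 (1.14) no longer passed. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385, minus strand), the gene of the Ki-67 antigen, stood at 9.89 ± 7.53 CPM against 2.05 ± 1.80 CPM. Its log2 fold change of 2.22 (SE 0.67) did not pass (adjusted p = 0.104, and adjusted p = 0.00571 with the donor as a block). CDK1 (2.23) and the mitotic activator FOXM1 (1.18) passed only with that block (adjusted p = 0.0909 and 0.0941 without it, 0.000946 and 0.0105 with it). Among genes that fell, the angiotensinogen gene AGT had a log2 fold change of −2.08 (adjusted p = 0.00256), APOBEC2 of −1.82 (adjusted p = 0.0164) and the lipolysis inhibitor G0S2 of −1.55 (adjusted p = 0.00675). VGF (ENSG00000128564, chromosome 7, 101162509 to 101165593, minus strand), a granin of secretory granules, fell from 722 ± 107 to 237 ± 59.5 CPM (log2 fold change −1.61, adjusted p = 0.00921). CDKN1C, the inhibitor p57 that holds beta cells out of cycle, stood at 168 ± 50.6 CPM against 336 ± 157 CPM (−0.995, adjusted p = 0.119, and 0.000789 with the donor block). GCG, the glucagon gene of alpha cells, stood at 26261 ± 11516 CPM in these cells against 9147 ± 3166 CPM (1.52, adjusted p = 0.114, and 9.85e-05 with the donor block).

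Across 17424 genes tested in beta-like cells, 361 changed after harmine by edgeR, 186 up and 175 down. With the donor as a block the counts were 1590 and 1703, and DESeq2 gave 431 and 403. Of the G2/M genes, 7 of 58 rose and 1 fell (37 and 1 adjusted over the list alone), with a median log2 fold change of 1.35 (camera adjusted p = 2.98e-28, and adjusted p = 0.253 with an estimated correlation). None of the 47 G1/S genes passed, over all genes or adjusted over the list alone, and their median was 0.51 (adjusted p = 1.39e-06, and adjusted p = 0.504 with an estimated correlation). Of the cyclins and their partners, 0 of 18 passed (3 adjusted over the list alone, median 0.40, adjusted p = 0.000161, and adjusted p = 0.253 with an estimated correlation). The donor block brought the G2/M count to 38 up and 1 down and the G1/S count to 15. The beta cell identity list had 7 of 27 genes up and none down (10 up and 1 down adjusted over the list alone), with a median of 0.45 and adjusted p = 9.57e-14, which held with an estimated correlation (adjusted p = 0.00381) but not with the donor block in addition (adjusted p = 0.0529). DDB2 and AEN, 2 of 20 p53 targets, rose by 0.73 and 0.74 (adjusted p = 0.0317 and 0.0326; list median 0.43, adjusted p = 1.17e-05, and adjusted p = 0.316 with an estimated correlation; 6 adjusted over the list alone). The alpha cell identity list had 1 of 19 genes up (4 adjusted over the list alone; median 0.35, adjusted p = 0.000876, and adjusted p = 0.541 with an estimated correlation). Secretory genes fell as a list through 1 of 15 genes, VGF, which alone also passed when adjusted over the list alone (median −0.36, adjusted p = 0.0451, and adjusted p = 0.504 with an estimated correlation). With the donor block 4 further lists passed: TGF-beta and SMAD targets (adjusted p = 0.0124), cAMP and CREB targets (0.0294), interferon genes (0.0231) and oxidative stress genes (0.0104). None did so with an estimated correlation in addition (0.405, 0.257, 0.330 and 0.158). No other of the 27 lists passed.

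G2/M UMIs per cell, not corrected for depth, were also measured in a class of another lineage. Over the 12 treated libraries, G2/M genes gained 1.12 ± 2.91 UMIs per mast-like cell over DMSO (mean and SD of 4 donors, 95% interval −3.51 to 5.74), against 2.41 ± 1.495 per beta-like cell and 13.2 ± 5.53 per alpha-like cell. The mast-like gain rested on LY364947 replicate 1 (21.6), without which it was −0.911 (−3.05 to 1.23). Judged by GCG, RNA of alpha-like cells would bring a median of 79.1% of the beta-like rise in CPM. Donors 1 and 3 had Cell Ranger 6 and donors 2 and 4 version 7, so that version and donor cannot be separated. In beta-like cells the G2/M median after harmine was 1.22 under version 6 and 1.504 under version 7, and the G1/S median was 0.49 and 0.30. With 2 libraries per group, 3 and 2 genes passed the threshold.

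**Figure D1:**
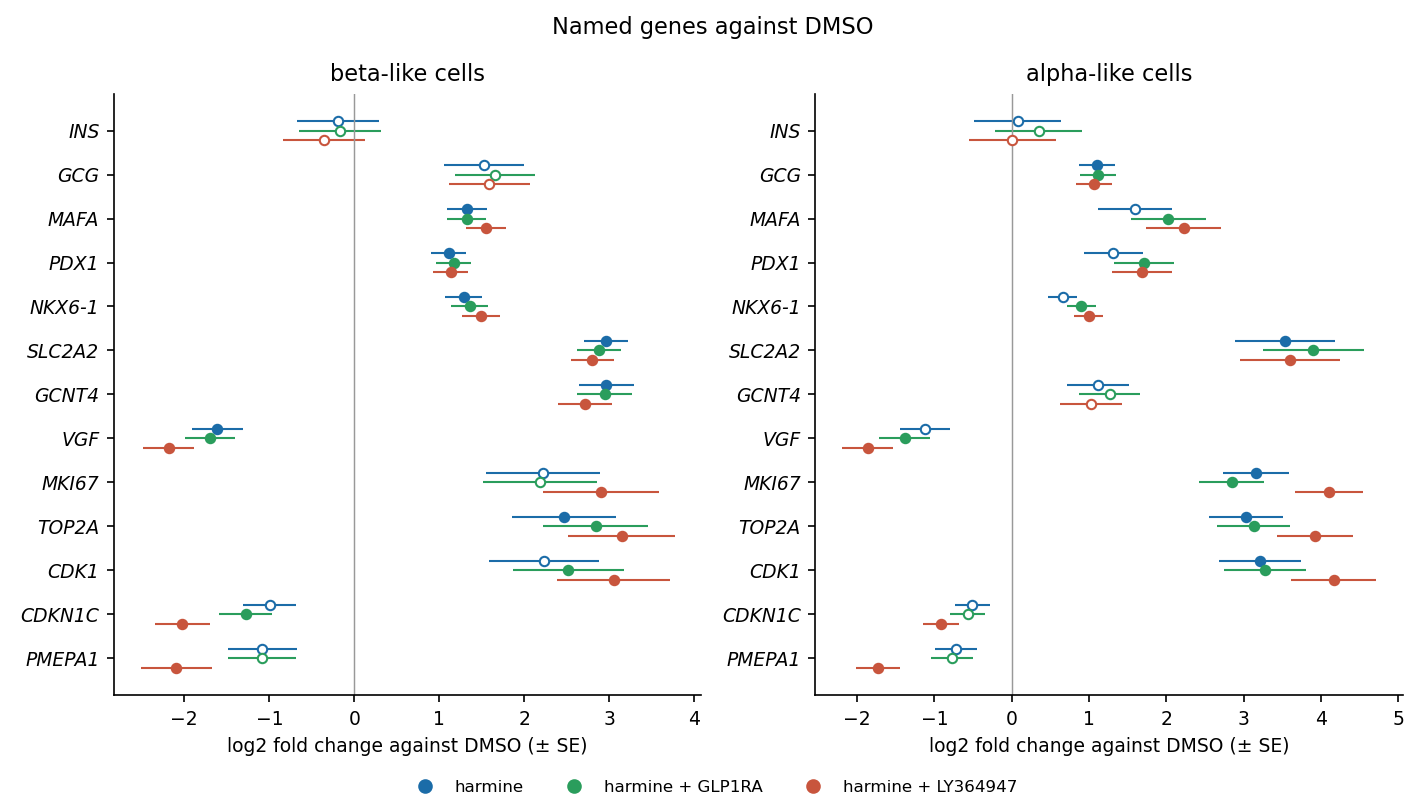
Log2 fold change against DMSO with its SE (bars) for 13 genes in beta-like and alpha-like cells after each of the 3 treatments, from sums over 4 libraries per group. Filled points have an adjusted p under 0.05; in beta-like cells after harmine SLC2A2 and GCNT4 rose (both 2.96) and VGF fell (−1.61).

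In alpha-like cells cell-cycle genes from DNA replication to mitosis rose after harmine. MKI67 rose from 4.90 ± 1.16 to 44.1 ± 25.9 CPM (log2 fold change 3.16, SE 0.43, adjusted p = 0.000356, n = 4). E2F1 (ENSG00000101412, chromosome 20, 33675683 to 33686404, minus strand), which switches on the genes of S phase, rose by 3.50 (SE 0.33, adjusted p = 5.61e-05), and the phosphatase CDC25A, which frees CDK2, by 2.38 (adjusted p = 0.000106). The replication genes DTL, CLSPN, FAM111B and MCM6 rose by 3.29, 3.21, 3.40 and 2.08 (adjusted p = 0.0001, 5.61e-05, 0.000354 and 0.000106). The mitotic genes AURKB, CENPU, CDK1, NUSAP1, TOP2A and FOXM1 rose by 3.27, 3.23, 3.21, 3.08, 3.03 and 2.52 (largest adjusted p among them, CDK1, 0.00186). GCG (ENSG00000115263, chromosome 2, 162142873 to 162152404, minus strand), the hormone of this cell type, rose by 1.11 (SE 0.24, adjusted p = 0.0123), while INS stood at a log2 fold change of 0.08 (adjusted p = 0.978).

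Other genes fell in alpha-like cells after harmine. The bombesin-like peptide gene NMB fell by 1.35 on the log2 scale (adjusted p = 0.0152) and the keratin KRT7 by 1.63 (adjusted p = 0.0319). The thioredoxin reductase TXNRD1 (−0.75, adjusted p = 0.0152) and the granin SCG3 (−0.68, adjusted p = 0.0192) were lower. SAA1, an acute-phase protein, had a log2 fold change of −4.87 (adjusted p = 0.0325), which rested on a level of 291 CPM in DMSO replicate 1. Without that library it was −2.30 (adjusted p = 0.222). The change of CDKN1C was −0.51 (adjusted p = 0.28, and 0.00959 with the donor block) and that of VGF −1.12 (adjusted p = 0.0615, and 8.17e-06 with the block).

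Of 16301 genes tested in alpha-like cells, 680 changed after harmine, 425 up and 255 down, with 1690 and 1855 under the donor block and 578 and 477 by DESeq2. G1/S genes rose in 34 of 47 cases (40 adjusted over the list alone), with a median of 1.64 (camera adjusted p = 1.63e-76, and adjusted p = 0.00497 with an estimated correlation). For G2/M genes the count was 47 of 58 (50 up and 1 down adjusted over the list alone), with a median of 2.55 (adjusted p = 2.34e-83, and adjusted p = 0.0165 with an estimated correlation). The cyclin list had 7 of 17 genes up (10 adjusted over the list alone), CDK6, CDC25A, E2F1, E2F2, E2F7, MYBL2 and FOXM1, and a median of 0.80 (adjusted p = 2.19e-16, and adjusted p = 0.00155 with an estimated correlation). Cell-cycle inhibitors passed as a list with none of 16 members past the threshold (median 0.35, adjusted p = 0.0294, and adjusted p = 0.093 with an estimated correlation). The beta cell identity list had 2 of 27 genes up (10 up and 1 down adjusted over the list alone), SLC2A2 by 3.53 (adjusted p = 0.00378) and NPTX2 by 1.22 (adjusted p = 0.00371). Its median was 0.28, with adjusted p = 0.00113 (adjusted p = 0.537 with an estimated correlation). The p53 targets were up through DDB2 (0.64, adjusted p = 0.0476; list median 0.40, adjusted p = 0.00381, and adjusted p = 0.537 with an estimated correlation). Lists with negative medians were cholesterol synthesis (−0.32, adjusted p = 0.00204, none of 16 genes, 3 adjusted over the list alone) and oxidative stress (−0.61, adjusted p = 0.0112, 1 of 13, 2 adjusted over the list alone). The secretory genes were a further one (−0.47, adjusted p = 0.000617, 1 of 15, 2 adjusted over the list alone). With an estimated correlation these 3 had adjusted p = 0.132, 0.537 and 0.053. The cAMP and CREB targets passed only with the donor block (adjusted p = 1.99e-05), and no other list of the 27 passed.

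Taking all INS in alpha-like sums as RNA of beta-like cells, that RNA amounted to a median of 92.5% of the rise of 8 beta cell genes there (96 pairs of gene and treated library), from 36.9% for FOXA2 to 117.4% for SLC2A2. Under Cell Ranger 6 the alpha-like medians after harmine were 1.66 for G1/S genes and 2.40 for G2/M genes, and under version 7 they were 1.75 and 2.47. With 2 libraries per group, 0 genes passed under version 6 and 234 under version 7.

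**Figure D2:**
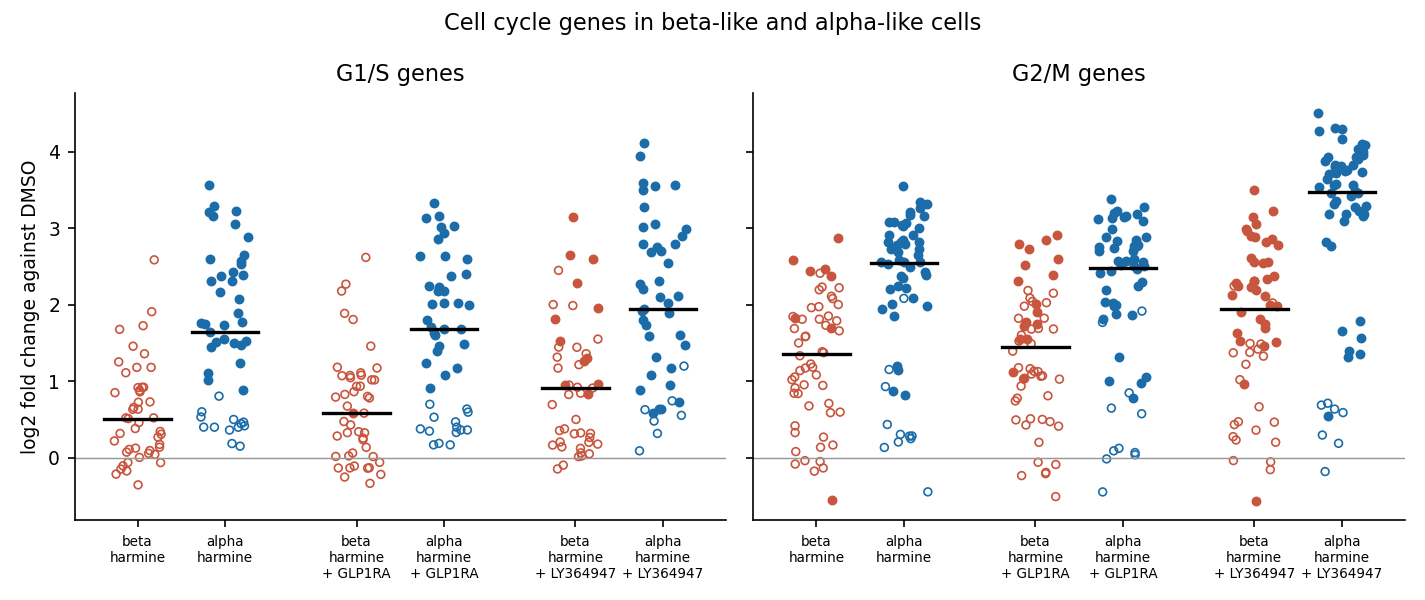
Log2 fold change against DMSO of each G1/S and G2/M gene (points) in beta-like and alpha-like cells after each of the 3 treatments, with the list median as a bar and filled points for an adjusted p under 0.05. The G2/M median was 1.35 in beta-like cells and 2.55 in alpha-like cells after harmine, and 1.94 and 3.47 after harmine with LY364947.

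Alpha-like and beta-like responses were compared as the difference between their fold changes. Replication genes gained more in alpha-like cells. Of 47 G1/S genes, 17, 10 and 17 had the higher value in alpha-like cells after harmine, with GLP1RA and with LY364947 (42, 38 and 37 adjusted over the list alone), and of 58 G2/M genes 14, 5 and 28 (31, 27 and 47). For G1/S genes the median difference (alpha-like minus beta-like) was 1.12 after harmine, 0.88 with GLP1RA and 0.92 with LY364947 (adjusted p = 1.22e-58, 4.70e-48 and 3.70e-46), and it held with an estimated correlation (adjusted p = 0.0019, 0.00506 and 0.00261). For G2/M genes the median difference was 0.82, 0.73 and 1.29 (adjusted p = 8.32e-40, 1.54e-28 and 2.58e-78). It had adjusted p = 0.0503, 0.0908 and 0.00261 with an estimated correlation. MCM6 rose by 1.63 more in alpha-like cells after harmine (adjusted p = 0.0109) and AURKB by 2.03 more (adjusted p = 0.0206). The difference of GCNT4 (−1.87, adjusted p = 0.000772) was negative. Cyclins (0.47, 0.34 and 0.26), alpha identity (−0.36, −0.44 and −0.42), cholesterol synthesis (−0.34, −0.22 and −0.24) and hypoxia genes (−0.13, −0.10 and −0.07) also passed in all 3 treatments, none with an estimated correlation. Without passing that test either, beta identity (−0.08) and cAMP targets (0.29) passed after harmine, oxidative phosphorylation after harmine (−0.14) and with GLP1RA (−0.13), and immediate-early (0.13) and oxidative stress genes (−0.28) with LY364947. Inhibitors passed with GLP1RA (0.18) and with LY364947 (0.22), the latter also with an estimated correlation (adjusted p = 0.00261). In all, 149 of 17866 genes differed between the classes after harmine (95 with the higher value in alpha-like cells), 96 with GLP1RA (63) and 273 with LY364947 (211). With the donor as a block these counts were 1725, 1683 and 2069.

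Shares of cells with an MKI67 or TOP2A UMI were taken after thinning to 2000 UMIs. In alpha-like cells the share was 1.56% ± 0.669 after DMSO, 7.85% ± 3.04 after harmine, 8.71% ± 4.05 with GLP1RA and 14.5% ± 4.83 with LY364947, higher than DMSO in 4 of 4 donors each time. The exact permutation test gave p = 0.0286 for each of the 3, two-sided, the smallest that 4 against 4 libraries allow, and adjusted p = 0.0643 over 9 tests. In beta-like cells the share was 1.81% ± 1.46, 3.71% ± 1.16, 4.72% ± 2.13 and 6.64% ± 3.02, higher in 3, 3 and 4 of 4 donors (exact permutation p = 0.0857, 0.0857 and 0.0286, adjusted p = 0.129, 0.129 and 0.0643). These differences of 1.91, 2.92 and 4.83 points were 2.96, 4.19 and 5.77 without replicate 1 and 1.34, 1.88 and 3.14 without replicate 3. In ductal-like cells it was 1.99% ± 3.26, 2.57% ± 2.18, 3.41% ± 2.71 and 6.42% ± 1.19 (exact permutation p = 0.743, 0.486 and 0.114, higher in 2, 3 and 3 donors). As a background, delta-like cells had 1.40% ± 1.65, 2.38% ± 2.02, 2.71% ± 1.82 and 5.72% ± 0.777. Of mast-like cells only 5, 4, 4 and 12 had such a UMI, pooled 3.42%, 3.28%, 2.52% and 7.10%. Library means were 1.26%, 5.53% (replicate 3 had no cell left), 2.50% and 3.35%. Median depths by group were 5260.5, 7027, 3942 and 2958.5 UMIs in beta-like cells and 10217, 9955, 7067 and 8877 in alpha-like cells. Without thinning the shares were 5.52%, 8.06%, 9.35% and 12.2% in beta-like cells and 5.11%, 14.2%, 13.9% and 22.04% in alpha-like cells. Thinning left out 15.3%, 19.1%, 28.05% and 38.8% of beta-like cells and 2.98%, 3.61%, 4.41% and 11.1% of alpha-like cells.

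**Figure D3:**
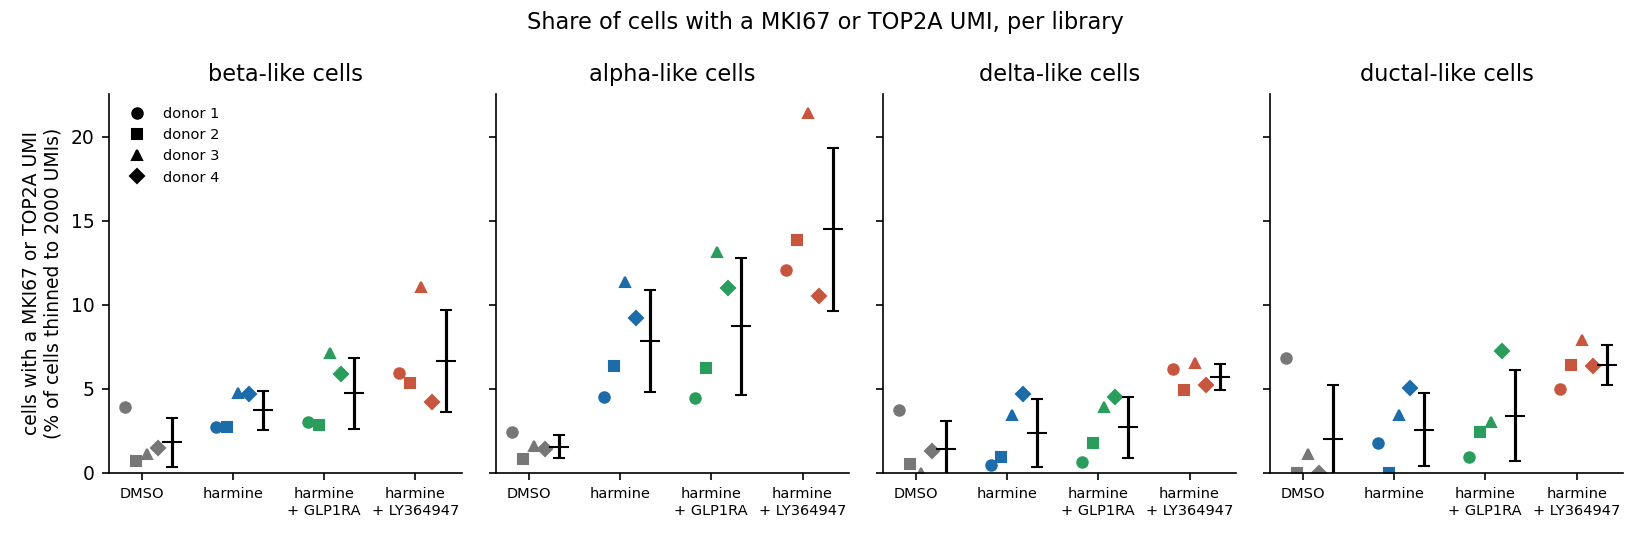
Percent of cells with an MKI67 or TOP2A UMI after thinning to 2000 UMIs, in beta-like, alpha-like, delta-like and ductal-like cells of each library (points, 4 donors per group), with the mean and SD; where the SD exceeds the mean its bar ends at 0. Alpha-like cells went from a mean of 1.56% after DMSO to 14.5% after harmine with LY364947, and delta-like cells, which were not tested, from 1.40% to 5.72%.

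Harmine with GLP1RA was compared with DMSO in the same way. In beta-like cells 7 of 27 genes of beta cell identity, 17 of 58 G2/M genes and 4 of 20 p53 targets rose, and VGF and CDKN1C fell. SLC2A2 rose by 2.88 (SE 0.26, adjusted p = 2.7e-05), GCNT4 by 2.94 (SE 0.32, adjusted p = 0.000174), MAFA by 1.32 (adjusted p = 0.00578) and NKX6-1 by 1.36 (adjusted p = 0.00327). IGFBP2, a carrier of insulin-like growth factors, rose from 50.4 ± 13.6 to 209 ± 114 CPM (2.05, adjusted p = 0.0115, n = 4). NUSAP1 (2.92), TOP2A (2.84), CENPF (2.79), CDK1 (2.52) and FOXM1 (1.31) passed (adjusted p = 0.00297, 0.0193, 0.0165, 0.0452 and 0.0495), as did GMNN, which guards against re-replication (0.59, adjusted p = 0.0335). MKI67 had a log2 fold change of 2.19 (adjusted p = 0.0899, and 0.00288 with the donor block) and GCG one of 1.65 (adjusted p = 0.068, and 4.22e-05 with the block). RPS27L and DDB2, both p53 targets, rose by 0.90 and 0.83 (adjusted p = 0.00896 and 0.0121). AGT had a log2 fold change of −2.31 (adjusted p = 0.00129), APOBEC2 of −2.05 (adjusted p = 0.00703), and VGF of −1.70 (adjusted p = 0.00549). ENPP2 (−1.58, adjusted p = 0.0119), SPP1 (−1.43, adjusted p = 0.035) and CDKN1C (−1.28, 138 ± 34.1 against 336 ± 157 CPM, adjusted p = 0.0348) fell as well. INS stood at −0.17 (adjusted p = 0.91).

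For beta-like cells given harmine with GLP1RA, 578 genes passed, 310 up and 268 down, with 2310 and 2094 under the donor block and 565 and 560 by DESeq2. G2/M genes had 17 of 58 up (37 up and 1 down adjusted over the list alone), a median of 1.44 and adjusted p = 2.89e-26 (adjusted p = 0.305 with an estimated correlation). Of G1/S genes 1 of 47 passed, GMNN (10 adjusted over the list alone), with a median of 0.59 and adjusted p = 1.04e-06 (adjusted p = 0.576 with an estimated correlation). The block raised these counts to 42 and 23. Cyclins had 3 of 18 up, E2F2, E2F7 and FOXM1 (5 adjusted over the list alone; median 0.40, adjusted p = 0.000286, and adjusted p = 0.305 with an estimated correlation). The p53 targets had 4 of 20 up, AEN, RPS27L, GDF15 and DDB2 (6 adjusted over the list alone; median 0.51, adjusted p = 1.49e-05, and adjusted p = 0.326 with an estimated correlation). Beta cell identity genes had 7 of 27 up (12 up and 1 down adjusted over the list alone), a median of 0.43 and adjusted p = 7.75e-10, which held with an estimated correlation (adjusted p = 0.0157) but not with the donor block in addition (adjusted p = 0.0788). Alpha identity (median 0.34, adjusted p = 0.00354), oxidative phosphorylation (0.25, adjusted p = 0.0434), TGF-beta targets (−0.67, adjusted p = 0.0434), oxidative stress (−0.27, adjusted p = 0.0434) and secretory genes (−0.31, adjusted p = 0.00989) also passed. They had 1, 0, 0, 0 and 1 members past the threshold (5, 0, 0, 0 and 3 adjusted over the list alone) and lost the call with an estimated correlation (adjusted p = 0.576, 0.745, 0.576, 0.576 and 0.49). The cAMP and CREB targets (0.0188) and progenitor genes (0.0187) passed only with the donor block, neither with an estimated correlation in addition (0.202 and 0.225), and no other of the 27 lists passed. Within Cell Ranger versions 6 and 7 the G2/M median was 1.23 and 1.599 and the G1/S median 0.70 and 0.44, with 1 and 3 genes past the threshold.

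In alpha-like cells given harmine with GLP1RA, 908 genes changed, 527 up and 381 down (2160 and 2186 with the donor block, 724 and 638 by DESeq2). Cell-cycle genes that rose included E2F1 at 3.44, CDK1 at 3.28, TOP2A at 3.13, CLSPN at 3.01, MKI67 at 2.85, HMGB2 at 2.57 and FOXM1 at 2.47 (largest adjusted p among them, CDK1, 0.00155). The inhibitors CDKN2D and RBL1 rose by 1.06 and 0.84 (adjusted p = 0.0166 and 0.0236). GCG rose by 1.12 (SE 0.24, adjusted p = 0.0103). MAFA (2.03, adjusted p = 0.0208), PDX1 (1.72, adjusted p = 0.0149), NKX6-1 (0.90, adjusted p = 0.00853) and SLC2A2 (3.90, adjusted p = 0.0018), which are beta cell genes and fall under the measure of beta-like RNA given for harmine, rose as well. SAA1 (−4.77, adjusted p = 0.0295; −2.19 and adjusted p = 0.2 without DMSO replicate 1), VGF (−1.39, adjusted p = 0.018) and NMB (−1.35, adjusted p = 0.0137) fell. SCG3 (−0.68, adjusted p = 0.018) and the sterol synthesis gene HMGCS1 (−0.54, adjusted p = 0.0423, and 0.128 without replicate 3 of this group) were lower. So were the interferon-induced IFIT2 (−2.04, adjusted p = 0.0444) and IFIT3 (−1.05, adjusted p = 0.0347).

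Among alpha-like lists after harmine with GLP1RA, G1/S genes had 33 of 47 up (38 adjusted over the list alone), a median of 1.68 and adjusted p = 1.02e-61, and G2/M genes 47 of 58 (52 up and 1 down adjusted over the list alone), a median of 2.48 and adjusted p = 5.84e-69. Both held with an estimated correlation (adjusted p = 0.0118 and 0.0318), as did the cyclins (7 of 17, 9 adjusted over the list alone; median 0.70, adjusted p = 7.64e-14, and 0.00362 estimated). The secretory genes held too (2 of 15 down, 2 adjusted over the list alone; median −0.55, adjusted p = 0.000305, and 0.0452 estimated). Beta cell identity genes had 8 of 27 up (10 up and 1 down adjusted over the list alone), a median of 0.44 and adjusted p = 6.63e-05 (adjusted p = 0.425 with an estimated correlation). Inhibitors (median 0.39, adjusted p = 0.0411), p53 targets (0.30, adjusted p = 0.0147), cholesterol synthesis (−0.35, adjusted p = 0.00282), interferon genes (−0.45, adjusted p = 0.0489) and oxidative stress genes (−0.50, adjusted p = 0.0393) passed. They had 2, 1, 1, 2 and 1 members past the threshold (2, 2, 4, 3 and 2 adjusted over the list alone) and adjusted p = 0.116, 0.732, 0.151, 0.281 and 0.643 with an estimated correlation. The cAMP targets (0.000246) and apoptosis genes (0.0403) passed only with the donor block, the latter not with an estimated correlation in addition (0.333), and no other of the 27 lists passed. Under Cell Ranger 6 and 7 the G1/S median was 1.603 and 1.70 and the G2/M median 2.17 and 2.58, with 0 and 239 genes past the threshold.

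Harmine with LY364947 was compared with DMSO too. In beta-like cells 36 of 58 G2/M genes rose, 7 of 28 TGF-beta targets fell, and 2 of 13 acinar genes rose. MKI67 rose from 2.05 ± 1.80 to 15.6 ± 12.1 CPM (2.90, SE 0.68, adjusted p = 0.022, n = 4). CENPF (3.50), NUSAP1 (3.23), TOP2A (3.14), CDK1 (3.05), CENPU (2.60), PRC1 (2.23), PTTG1 (2.09), FOXM1 (1.88) and GMNN (0.96) rose (largest adjusted p among them, PTTG1, 0.0182). CDKN1C (ENSG00000129757, chromosome 11, 2883213 to 2885773, minus strand) fell from 336 ± 157 to 82.7 ± 22.5 CPM (−2.02, SE 0.32, adjusted p = 0.00182), and CDKN1A, the inhibitor p21, stood at −0.96 (adjusted p = 0.165, and 6.25e-05 with the donor block), but at −0.48 (adjusted p = 0.58) without DMSO replicate 1. The TGF-beta targets PMEPA1 and SKIL fell by 2.09 and 1.31 on the log2 scale (adjusted p = 0.00877 and 0.0141). SPP1, which encodes osteopontin, fell from 440.0 ± 141 to 37.0 ± 19.1 CPM (−3.57, adjusted p = 0.000124). PRG4 (−4.06), TGM2 (−3.37), AGT (−2.99) and VGF (−2.18) were lower too (adjusted p = 0.00858, 0.00393, 0.000128 and 0.000736). SLC2A2 (2.80), WSCD2 (2.09), IL17RB (1.96), MAFA (1.55) and NKX6-1 (1.49) rose (adjusted p = 1.93e-05, 0.0222, 0.000175, 0.0013 and 0.00105). INS stood at −0.36 (adjusted p = 0.821) and GCG at 1.59 (adjusted p = 0.0674, and 5.12e-05 with the block). PNLIP, the pancreatic lipase of acinar cells, went from 0.511 ± 0.591 to 13.98 ± 12.4 CPM (4.78, adjusted p = 0.00915), CPA1 rose by 3.46 (adjusted p = 0.0408), and PRSS1 stood at 3.40 (adjusted p = 0.0753, and 3.19e-05 with the block).

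Beta-like cells given harmine with LY364947 had 831 genes changed, 412 up and 419 down (1960 and 2137 with the donor block, 643 and 699 by DESeq2). G2/M genes had 36 of 58 up and 1 down (47 and 1 adjusted over the list alone), a median of 1.94 and adjusted p = 2.27e-39. Of G1/S genes 12 of 47 were up (25 adjusted over the list alone), with a median of 0.91 and adjusted p = 3.91e-15. With an estimated correlation these lists had adjusted p = 0.0889 and 0.195. The donor block gave 47 and 30 genes up. Cyclins had 5 of 18 up, E2F1, E2F2, E2F7, MYCN and FOXM1 (6 adjusted over the list alone; median 0.57, adjusted p = 1.86e-07, and adjusted p = 0.0599 with an estimated correlation). TGF-beta and SMAD targets had 7 of 28 down (13 adjusted over the list alone), a median of −0.93 and adjusted p = 9.44e-10 (adjusted p = 0.0599 with an estimated correlation; 18 down with the block). Beta cell identity genes had 8 of 27 up and 1 down, UCN3 (10 and 1 adjusted over the list alone), a median of 0.37 and adjusted p = 2.81e-08, and held with an estimated correlation (adjusted p = 0.0409) but not with the donor block in addition (adjusted p = 0.115). Acinar genes had 2 of 13 up (8 adjusted over the list alone, 12 with the block), a median of 2.96 and adjusted p = 6.72e-07 (adjusted p = 0.438 with an estimated correlation). The p53 targets (median 0.45, adjusted p = 0.00134), alpha identity genes (0.47, adjusted p = 0.00494) and secretory genes (−0.40, adjusted p = 0.00318) passed. They had 2, 1 and 1 members past the threshold (6, 2 and 2 adjusted over the list alone) and adjusted p = 0.438, 0.725 and 0.303 with an estimated correlation. With the donor block cAMP targets (0.04), progenitor genes (0.0444) and oxidative stress genes (0.0158) passed too, none with an estimated correlation in addition (0.122, 0.169 and 0.122), and no other list of the 27 did. Within Cell Ranger versions 6 and 7 the G2/M median was 2.01 and 1.68 and the G1/S median 0.995 and 0.399, with 15 and 7 genes past the threshold.

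In alpha-like cells under harmine with LY364947, 40 of 47 G1/S and 51 of 58 G2/M genes rose, 7 of 27 TGF-beta targets fell, and of 13 acinar genes 3 rose and 1 fell. MKI67 rose from 4.90 ± 1.16 to 84.6 ± 43.5 CPM (4.11, SE 0.44, adjusted p = 2.24e-05, n = 4), and CDK1, CENPF, ASPM, TOP2A, E2F1, CLSPN and FOXM1 rose by 4.17, 4.08, 4.01, 3.93, 3.92, 3.59 and 3.37 (largest adjusted p among them, CDK1, 0.000119). The inhibitors CDKN2D and RBL1 rose by 1.38 and 1.14 (adjusted p = 0.00211 and 0.00228), and CDKN1C fell by 0.91 on the log2 scale (adjusted p = 0.0251). GCG rose by 1.06 (adjusted p = 0.0114). Falls included PRG4 (−2.66, adjusted p = 0.000255), TGM2 (−1.98, adjusted p = 0.0345) and VGF (−1.87, adjusted p = 0.00183). Further falls were those of PMEPA1 (−1.73, adjusted p = 0.00101), TGFB1 (−1.44, adjusted p = 0.00709), UCN3 (−0.999, adjusted p = 0.00886), GCLC (−0.84, adjusted p = 0.0192) and SAA1 (−6.02, adjusted p = 0.0102; −3.42 and adjusted p = 0.0579 without DMSO replicate 1). Of beta cell genes, SLC2A2 (3.61), MAFA (2.23), PDX1 (1.68) and NKX6-1 (0.995) rose (adjusted p = 0.00215, 0.00995, 0.0144 and 0.00299). PNLIP and CPA1 rose by 4.32 and 3.38 (adjusted p = 0.0052 and 0.0387), whereas SPINK1, a trypsin inhibitor that endocrine cells also express, fell from 779 ± 311 to 229 ± 19.1 CPM (−1.77, adjusted p = 0.00648).

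In these alpha-like cells 946 genes changed, 551 up and 395 down (1902 and 2013 with the block, 695 and 616 by DESeq2). G2/M genes had 51 of 58 up (54 adjusted over the list alone), a median of 3.47 and adjusted p = 3.20e-123. G1/S genes had 40 of 47 up (46 adjusted over the list alone), a median of 1.95 and adjusted p = 2.85e-86. Cyclins had 6 of 17 up (11 adjusted over the list alone), a median of 0.94 and adjusted p = 1.01e-19. These 3 held with an estimated correlation (adjusted p = 0.00397, 0.00366 and 0.00108). TGF-beta targets had 7 of 27 down (12 down and 1 up adjusted over the list alone; median −0.72, adjusted p = 3.28e-06, and adjusted p = 0.136 with an estimated correlation). Acinar genes had 3 of 13 up, PRSS1, CPA1 and PNLIP, and 1 down, SPINK1 (10 and 1 adjusted over the list alone; median 2.88, adjusted p = 0.000196, and adjusted p = 0.391 with an estimated correlation). Beta cell identity genes had 7 of 27 up and 1 down (9 and 1 adjusted over the list alone; median 0.34, adjusted p = 0.000108, and adjusted p = 0.352 with an estimated correlation). Inhibitors (0.34, adjusted p = 0.0307), p53 targets (0.37, adjusted p = 0.0307), cholesterol synthesis (−0.28, adjusted p = 0.00809), oxidative stress (−0.72, adjusted p = 0.00266) and secretory genes (−0.31, adjusted p = 0.00615) passed. They lost the call with an estimated correlation (adjusted p = 0.136, 0.697, 0.212, 0.352 and 0.136). The cAMP targets passed only with the block (0.00217), and no other list did. Under Cell Ranger 6 and 7 the G2/M median was 3.50 and 3.33 and the G1/S median 2.03 and 1.94, with 48 and 366 genes past the threshold.

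Both combinations were compared with harmine alone. GLP1RA changed 0 genes in beta-like cells by edgeR (48 at an unadjusted p under 0.05, 0 by DESeq2 and 0 with the donor block) and 0 in alpha-like cells (73 unadjusted, 0 by DESeq2 and 0 with the block). Of the lists, only the interferon genes passed, in alpha-like cells (median −0.10, adjusted p = 0.0127, and adjusted p = 0.403 with an estimated correlation). LY364947 lowered 13 genes in beta-like cells and raised 0 (669 at an unadjusted p under 0.05, 13 up and 67 down by DESeq2, 131 and 353 with the block). Among them SPP1 had a log2 fold change of −2.96 (SE 0.37, adjusted p = 0.0053), the protease PRSS23 of −1.57 (adjusted p = 0.0147), KLHDC8A of −1.51 (adjusted p = 0.0152), EXPH5 of −1.48 (adjusted p = 0.0239) and BCR of −1.26 (adjusted p = 0.0053). In alpha-like cells 0 genes passed by edgeR (612 unadjusted), 27 by DESeq2 and 376 with the block. The lists with LY364947 over harmine in beta-like cells were G1/S (median 0.32, adjusted p = 1.83e-09), G2/M (0.52, adjusted p = 9.82e-10), cyclins (0.39, adjusted p = 0.00391), inhibitors (−0.16, adjusted p = 0.0407) and TGF-beta targets (−0.67, adjusted p = 1.35e-13). Further ones were interferon genes (0.40, adjusted p = 0.00867), immediate-early and heat-shock genes (−0.13, adjusted p = 0.0306) and acinar genes (2.91, adjusted p = 1.26e-22). With an estimated correlation these had adjusted p = 0.407, 0.65, 0.407, 0.407, 0.0528, 0.271, 0.661 and 0.116, and members passed adjusted over the list alone for G1/S (1 up), TGF-beta targets (6 down) and acinar genes (7 up). In alpha-like cells they were G1/S (0.29, adjusted p = 3.04e-10), G2/M (0.93, adjusted p = 4.38e-51), cyclins (0.24, adjusted p = 0.000728), TGF-beta targets (−0.69, adjusted p = 2.06e-11) and acinar genes (2.83, adjusted p = 3.90e-21). These had adjusted p = 0.414, 0.0728, 0.154, 0.0632 and 0.0632 under an estimated correlation. Adjusted over the list alone, 14 G2/M genes, 1 cyclin gene and 10 acinar genes rose and 5 TGF-beta targets fell. With the donor block further lists passed over harmine. With GLP1RA they were oxidative phosphorylation in beta-like cells (up, 0.0487), and in alpha-like cells beta identity (up, 0.000509), oxidative phosphorylation (up, 0.00944), NF-kB (down, 0.000509) and acinar genes (up, 0.0451). With LY364947 they were beta identity in beta-like cells (down, 0.0221), and in alpha-like cells beta identity (up, 0.014), NF-kB (down, 0.0131), immediate-early (down, 0.0468) and oxidative stress genes (down, 0.0468). None of these did so with an estimated correlation in addition (0.852 in beta-like and 0.864 for each list in alpha-like cells with GLP1RA, and 0.535, then 0.470, 0.470, 0.370 and 0.356 with LY364947). No other of the 27 lists passed over harmine. Without replicate 3 of LY364947 its medians over harmine were 0.16 for G2/M genes in beta-like cells and 0.14 and 0.56 for G1/S and G2/M genes in alpha-like cells, and for G1/S genes 0.17 in beta-like cells without its replicate 1 and 0.44 in alpha-like cells without its replicate 4. The G2/M median over harmine was 0.75 under Cell Ranger 6 and 0.07 under version 7 in beta-like cells, and 1.03 and 0.67 in alpha-like cells.

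Acinar-like cells, the enzyme-secreting cells of the pancreas, made up 0.597% ± 0.372 of cells after DMSO, 0.814% ± 0.586 after harmine, 0.924% ± 0.664 with GLP1RA and 13.4% ± 11.98 with LY364947. The last share was 22.4 times that of DMSO and higher in 4 of 4 donors (exact permutation p = 0.0286, adjusted p = 0.617 over 36 tests). The difference of 12.8 points ran from 7.55 without replicate 4 to 16.6 without replicate 3, and edgeR on the cell counts gave a log2 fold change of 4.47 (adjusted p = 0.00608). Over 5 times the acinar UMIs of the highest other class were held by 42.8%, 10.2%, 83.8% and 47.4% of acinar-like cells in the 4 LY364947 libraries. Cells with over 20 times as many were 0.455% ± 0.332 after DMSO and 2.36% ± 1.67 with LY364947, higher in 4 of 4 donors. Acinar UMIs also rose in cells of other classes. Over 12 acinar genes (SPINK1 left out), beta-like cells held 1.12 ± 1.05 UMIs per cell after DMSO, 0.994 after harmine, 0.859 with GLP1RA and 5.14 ± 2.86 with LY364947. Between DMSO and LY364947, alpha-like cells went from 1.18 ± 1.12 to 5.19 ± 2.97, delta-like cells from 1.07 to 5.20 and mesenchymal-like cells from 1.47 to 6.04.

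**Figure D4:**
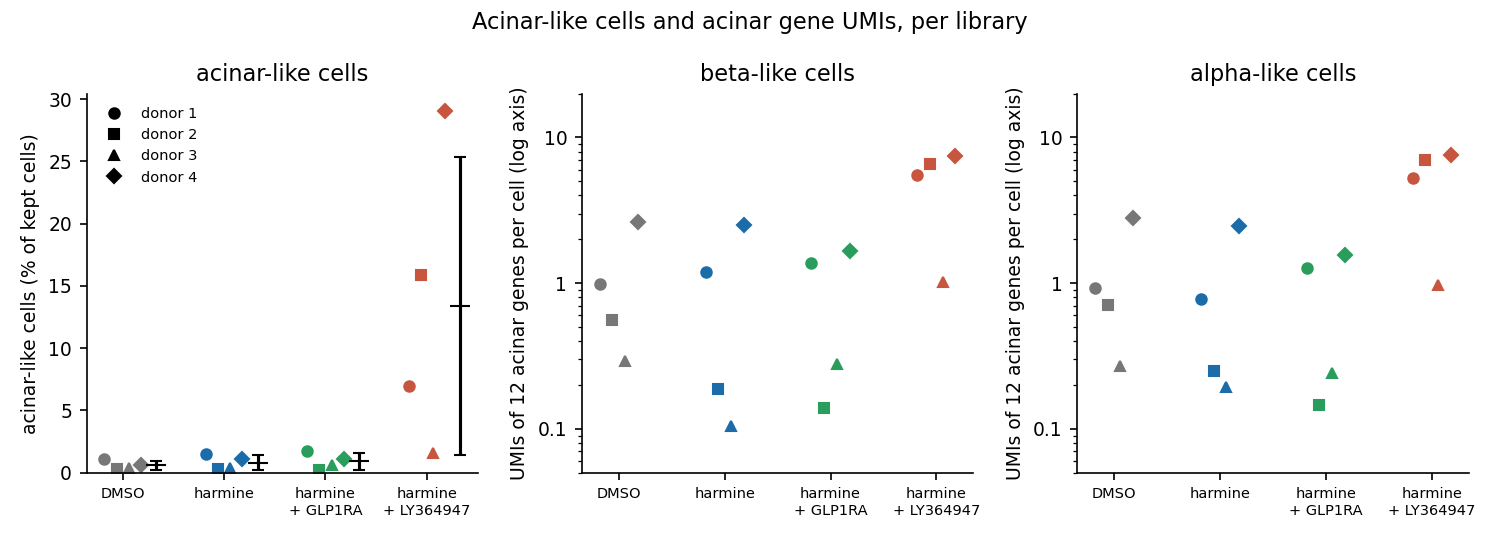
Acinar-like cells as percent of cells, and UMIs per cell of 12 acinar genes in beta-like and alpha-like cells, per library (points, 4 donors per group), with the mean and SD beside the shares and a log axis for UMIs. With LY364947 the acinar-like share was 13.4% against 0.597% after DMSO, and beta-like cells held 5.14 acinar UMIs against 1.12.

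No class share passed the permutation test. Beta-like cells were 30.5% ± 8.63 of cells after DMSO, 26.9% ± 8.97 after harmine, 27.2% ± 11.1 with GLP1RA and 26.5% ± 13.5 with LY364947, higher than DMSO in 0, 1 and 1 of 4 donors. Unnamed clusters 1, 9 and 20, which scored highest for beta, are left out. With classes from each cell's own markers the beta-like share rose instead, by 8.57, 11.3 and 5.24 points. Alpha-like cells were 18.3% ± 8.51, 23.6% ± 9.94, 23.1% ± 12.2 and 19.1% ± 8.65, higher in 4, 3 and 2 donors (exact permutation p = 0.429, 0.571 and 0.914). Mesenchymal-like cells were 13.9% ± 5.70, 9.03% ± 4.69, 6.19% ± 3.79 and 7.22% ± 4.03, lower than DMSO in 4 of 4 donors each time, which the exact permutation test did not pass (p = 0.229, 0.0857 and 0.143, adjusted p = 0.949, 0.617 and 0.857). Within the beta-like class, cluster 14 held 0.08%, 0.89%, 14.75% and 0.48% of cells by group, with 90.6% of its cells from 1 donor, and clusters 2, 4, 7 and 12 held the rest, cluster 7 with 16.3%, 25.6%, 15.7% and 14.4%. Cluster 10 held 6.64%, 10.0%, 15.4% and 16.6% of alpha-like cells, with 98.1% of its cells from 1 donor, and cluster 0 the rest. Clusters 7 and 12 drew 77.8% and 98.2% of their cells from 1 donor each. These percentages pool libraries, so that donors with more cells weigh more.

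Ductal-like and mesenchymal-like cells were compared with DMSO to see what the drugs do outside the endocrine cells. In ductal-like cells harmine lowered SAA1, SAA2 and ANGPTL4, and with LY364947 MUC6 and LYZ rose while TGFBI and FN1 fell. After harmine THBD rose by 2.62 (adjusted p = 0.0288), IAPP by 2.60 (adjusted p = 0.0419) and GCG by 1.97 (adjusted p = 0.0498), the last 2 being endocrine transcripts. SAA2 (−3.64, adjusted p = 0.0031), SAA1 (−3.08, adjusted p = 0.027), ANGPTL4, an inhibitor of lipoprotein lipase (−3.08, adjusted p = 0.0158), and the protease inhibitor CST6 (−2.95, adjusted p = 0.0158) fell. With GLP1RA, DLK1 (3.28), IAPP (2.90) and THBD (2.72) rose, and ANGPTL4 (−3.21), CCDC80 (−3.13) and the integrin ITGB6 (−2.39) fell (largest adjusted p among the 6, DLK1, 0.0178). With LY364947, the gastric-type mucin MUC6 rose from 4.58 ± 3.07 to 147 ± 127 CPM (4.92, SE 0.63, adjusted p = 0.000501), LYZ by 3.003 (adjusted p = 0.00123) and the endocrine genes MAFA and IAPP by 2.94 and 2.92 (adjusted p = 0.021 and 0.0151). ANGPTL4 fell from 301 ± 132 to 6.42 ± 2.92 CPM (−5.50, adjusted p = 0.000225), and TGFBI (−4.11), CST6 (−4.05) and FN1, fibronectin (−3.99), were lower (adjusted p = 0.000294, 0.000501 and 0.0281). Of 12849 genes tested, 114 passed after harmine (56 up), 233 with GLP1RA (117 up) and 195 with LY364947 (68 up), with 1947, 2557 and 2046 under the donor block and 332, 624 and 511 by DESeq2. The G2/M median differed in sign between pairs of donors. It was −1.05, −0.76 and −0.01 in donors 1 and 3 (Cell Ranger 6). In donors 2 and 4 (version 7) it was 1.44, 1.504 and 2.001.

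Mesenchymal-like cells had the most genes passing with LY364947. Harmine raised the stress cytokine GDF15 (2.48, adjusted p = 0.0105), the retinoic acid carrier CRABP2 (2.32, adjusted p = 0.0208) and the potassium channel KCNMA1 (2.19, adjusted p = 0.000486). It lowered IGFBP3 (−2.12, adjusted p = 0.0198), ECM1 (−1.62, adjusted p = 0.0178) and the activin binder FSTL3 (−1.56, adjusted p = 0.00665). With GLP1RA, GDF15 was up by 2.56 and IGFBP3 (−2.04), ITGBL1 (−1.92) and FSTL3 (−1.89) were down (largest adjusted p, IGFBP3, 0.0159). With LY364947 the FGF antagonist SPRY1 rose from 4.55 ± 1.10 to 62.9 ± 14.3 CPM (3.77, SE 0.35, adjusted p = 2.08e-05), and the Wnt regulators RSPO3 (3.66) and SFRP1 (3.63), the peptide ADM (3.37) and the pericyte marker RGS5 (3.27) rose (largest adjusted p, RGS5, 0.0214). KANK4 (−4.68), FOXS1 (−4.67), GDF6 (−3.73), the TGF-beta-induced inhibitor CDKN2B (−3.50) and ITGBL1 (−3.50) fell (largest adjusted p, KANK4, 0.00111). Of 15788 genes tested, 188 passed after harmine (120 up), 451 with GLP1RA (265 up) and 1343 with LY364947 (726 up), with 2889, 3660 and 5120 under the donor block and 499, 867 and 1907 by DESeq2.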

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

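Of the tests below, the one over splits of the libraries for genes changed in beta-like cells after harmine was chosen after the result was seen, as were the mean over donors for mast-like cells and the limits of 5 and 20 times for acinar-like cells. Values are from groups of 4 libraries.

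Mitotic genes were higher in the beta-like sums of treated libraries. Free RNA taken up by every droplet was tested in mast-like cells, a class of another lineage with 11 to 161 cells per treated library. Their rise was 46.3% of the rise per beta-like cell (95% interval −146% to 238% from the spread between donors), and −38.8% (−130% to 52.5%) without LY364947 replicate 1. In 8 of the 10 treated libraries with a beta-like rise the mast-like one was under 50% of it. The spread between donors leaves this source open, and it cannot be told apart from a rise within beta-like cells. RNA of alpha-like cells, judged by GCG, would bring a median of 79.1% of the rise in the 11 treated libraries that had one (64.3% after harmine, 74.8% with GLP1RA, 86.3% with LY364947), with 3 libraries under 50%, and cannot be told apart from such a rise either. Both tests take their sources as constant across droplets, which was not tested, and the first was not corrected for depth. Division of beta-like cells under harmine stays open, as untested.

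Beta cell genes were higher in the alpha-like sums of treated libraries. Taking all INS there as RNA of beta-like cells, that RNA would bring a median of 92.5% of the rise over 8 genes, from 36.9% for FOXA2 and 75.8% for NKX6-1 to 107.3% for IAPP and 117.4% for SLC2A2, with 11 of 96 pairs of gene and library under 50%. RNA of beta-like cells is therefore a candidate explanation for most of the rise. A gain of beta cell genes by alpha-like cells under the drugs stays open, and that RNA accounted for least in FOXA2.

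With LY364947, acinar genes were higher in beta-like and alpha-like sums, and acinar-like cells were more frequent. In those 4 libraries the largest of the beta-like, alpha-like, delta-like and mesenchymal-like classes held a median of 1.27 times the acinar UMIs per cell of the smallest, as free acinar RNA taken up by every droplet would give. Hormone transcripts in acinar-like cells were a median of 2.04 times those of other non-endocrine classes (2.10, 3.41, 1.98 and 1.30 in replicates 1 to 4), which did not decide whether other cells carrying acinar RNA were counted as acinar-like. A median of 45.1% of the acinar-like cells held over 5 times the acinar UMIs of the highest other class, so that free RNA is a candidate explanation for the remaining ones and for part of the rise. It is argued against for cells with over 20 times as many, whose share was 5.18 times that of DMSO. Cell filters and doublet removal are argued against, since the share was at least 8.9 times that of DMSO with doublets kept, with stricter filters and with classes from each cell's own markers. The wider naming of clusters, which counts cluster 13 as acinar-like, was not among these settings. Survival or growth of acinar cells with LY364947 stays open, as untested.

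Chance was tested over the 35 splits of 8 libraries into 4 and 4, of which 8 part all 4 donors. For genes changed against DMSO the real split was the only 1 with as many in each class. Every donor is in every group, and the 8 splits that part all donors are too few for a share under 0.05. Chance is therefore not excluded by these counts. The real counts were 361, 578 and 831 in beta-like cells (highest other 0, 0 and 2), 680, 908 and 946 in alpha-like cells (highest other 0 each), 114, 233 and 195 in ductal-like cells (12, 1 and 1) and 188, 451 and 1343 in mesenchymal-like cells (0 each). The same held for the 13 genes of beta-like cells with LY364947 over harmine (highest other 0), and over 25 splits for the differences between alpha-like and beta-like responses (149, 96 and 273, highest other 1, 0 and 0). Where the real count was 0 the splits decide nothing, since each gives at least as many. This was so with GLP1RA over harmine in both classes (highest other 0) and with LY364947 over harmine in alpha-like cells (highest other 9).

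For the medians of G1/S and G2/M genes in alpha-like cells the real split was the only 1 as large. They were 1.64, 1.68 and 1.95 for G1/S (highest other 0.99, 0.96 and 1.36) and 2.55, 2.48 and 3.47 for G2/M (1.66, 1.68 and 2.15). In beta-like cells the real split was the largest of 35, by a narrow margin, for G1/S with LY364947 (0.91, highest other 0.83). So it was for G2/M after harmine (1.35, 1.33) and with GLP1RA (1.44, 1.41). It was not for G1/S after harmine (0.51, 0.69) and with GLP1RA (0.59, 0.70) or for G2/M with LY364947 (1.94, 1.97). There 2 of 35 splits, the real one included, were as large. Since the 35 splits ignore that groups share donors, they exclude chance in neither class. Among the 8 splits that part all donors, too few for a share under 0.05, the real one was the largest throughout, with 0.33, 0.41 and 0.58 next for G1/S and 1.20, 1.41 and 1.41 for G2/M in beta-like cells. None of the larger other splits followed the Cell Ranger version.

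Of 528 groups of 4 libraries, 27 (5.11%) had 1 library far from the other 3, where chance gives about 1 in 20 groups, or 26.4. They fell on replicate 1 in 13 cases, replicate 2 in 3, replicate 3 in 6 and replicate 4 in 5. The share of ductal-like cells with an MKI67 or TOP2A UMI was 6.81% in DMSO replicate 1 against at most 1.15% in the others. In beta-like cells CDKN1A stood at 329 CPM after DMSO, 248.5 CPM after harmine and 234 CPM with GLP1RA in replicate 1. Also in beta-like cells, NKX6-1 was at 122 CPM with LY364947 in replicate 1, THBD at 266 CPM with GLP1RA in replicate 4, PRC1 at 16.1 CPM after harmine in replicate 3, AEN at 15.7 CPM with GLP1RA in replicate 1, G0S2 at 106 CPM after DMSO in replicate 2 and PNLIP at 1.39 CPM after DMSO in replicate 4.

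In alpha-like cells DMSO replicate 1 stood apart in SAA1 (291 CPM), GCG (53590 CPM) and DDB2 (18.2 CPM), and DMSO replicate 3 in NMB (39.2 CPM). With GLP1RA, replicate 4 had INS at 66120 CPM and KRT7 at 17.2 CPM, replicate 3 GCG at 250900 CPM and HMGCS1 at 12.7 CPM, and replicate 2 TGM2 at 114 CPM. NMB was at 12.2 CPM with LY364947 in replicate 3. In ductal-like cells CST6 was at 177 CPM with GLP1RA in replicate 3 and MAFA at 22.9 CPM after DMSO in replicate 4. In mesenchymal-like cells replicate 1 had RSPO3 at 7.11 CPM after DMSO and 22.8 CPM after harmine, and SPRY1 at 16.6 CPM and RGS5 at 53.9 CPM with GLP1RA, while CRABP2 was at 29.04 CPM after DMSO in replicate 2. Without its outlying library a call was lost for SAA1 (log2 fold changes −2.30, −2.19 and −3.42 without DMSO replicate 1) and for HMGCS1 with GLP1RA (−0.45 without replicate 3 of that group, adjusted p = 0.128).

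Some named genes differed in response (log2 fold change) between the classes, given as alpha-like minus beta-like cells. After harmine these were MCM6 (1.63), AURKB (2.03), PRC1 (1.05), GCNT4 (−1.87), C2CD4A (−1.32), NMB (−1.20) and ZNF703 (−0.98), with C2CD4A at adjusted p = 0.00467, PRC1 and ZNF703 at 0.0179 and NMB at 0.0328. With GLP1RA they were HMGB2 (1.545, adjusted p = 0.000176), GCNT4 (−1.73, adjusted p = 0.00247) and NMB (−1.25, adjusted p = 0.0323). With LY364947 they were CDKN1A (0.955, adjusted p = 0.00203), GMNN (0.63, adjusted p = 0.0276), PRC1 (1.53, adjusted p = 0.000963), FOXM1 (1.52, adjusted p = 0.017), PTTG1 (1.48, adjusted p = 0.0268) and TGM2 (1.30, adjusted p = 0.0404). The list medians differed by 1.12, 0.88 and 0.92 for G1/S genes and by 0.82, 0.73 and 1.29 for G2/M genes after harmine, with GLP1RA and with LY364947.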

How the results depend on the processing

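The wider naming of clusters, and leaving out a whole donor for the counts of genes changed, were chosen after the data were seen. For the shifts below the cause was not tested, except that fewer libraries are fitted when 1 is left out and that the donor block removes the spread between donors.

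Under the donor block (replicate block) the counts of genes changed were 3293, 4404 and 4097 in beta-like cells after harmine, with GLP1RA and with LY364947, 484 with LY364947 over harmine, 3545, 4346, 3915 and 376 in alpha-like cells, 1947, 2557 and 2046 in ductal-like cells, 2889, 3660 and 5120 in mesenchymal-like cells, and 1725, 1683 and 2069 for the difference between alpha-like and beta-like responses. Beyond these and the genes and lists named in the report, the block moved calls made with an estimated correlation. It ended that of beta identity in beta-like cells (adjusted p = 0.0529, 0.0788 and 0.115). In alpha-like cells it made those of inhibitors (0.0371 and 0.0498), oxidative stress (0.0371) and secretory genes (0.0164) after harmine or with GLP1RA, of oxidative stress and secretory genes with LY364947 (0.0256 each), of cAMP targets (0.00887, 0.0137 and 0.0256) and, over harmine, of TGF-beta targets and acinar genes (0.0469 each). For the difference between classes it added calls for inhibitors, TGF-beta targets, other hormones, immediate-early and secretory genes after harmine, for immediate-early genes with GLP1RA, and for TGF-beta targets and NF-kB with LY364947, none with an estimated correlation in addition. It changed no other call given here. DESeq2 gave 834, 1125, 1342 and 80 in beta-like cells, 1055 after harmine and 27 with LY364947 over harmine in alpha-like cells, 332, 624 and 511 in ductal-like cells and 499 and 867 in mesenchymal-like cells after harmine and with GLP1RA. The other 5 DESeq2 counts were within 1.5 times.

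With classes from each cell's own markers the counts were 22 in beta-like cells and 1 in alpha-like cells with LY364947 over harmine, and 38 and 75 in ductal-like cells after harmine and with GLP1RA. Without a filter on low counts, LY364947 over harmine gave 20 in beta-like cells and 1 in alpha-like cells, and with wider class names 37 in beta-like cells. RLE scaling and stricter filters left all 16 counts, and doublets kept all 19, within 1.5 times.

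With an estimated correlation 10 of 16 cell-cycle list calls were lost. They were G1/S genes (0.51, 0.59, 0.91 and, over harmine, 0.32) and G2/M genes (1.35, 1.44, 1.94 and 0.52) in beta-like cells, and both lists with LY364947 over harmine in alpha-like cells (0.29 and 0.93). RLE scaling, no filter on low counts, the donor block and wider names changed no call of these lists. Doublets kept turned the G2/M median of GLP1RA over harmine in beta-like cells to −0.0344, a list that had not passed.

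Of the shares, the difference in ductal-like cells with an MKI67 or TOP2A UMI after harmine went to −0.0698 points thinned to 1000 UMIs and to −1.16 not thinned. The acinar-like share after harmine went to −0.23 points with marker classes and −0.45 with wider names, where that with GLP1RA went to −0.87. The beta-like share rose by 8.57, 11.3 and 5.24 points with marker classes for harmine, GLP1RA and LY364947 instead of falling, and stood at 0.0825 with wider names with GLP1RA. None of these had passed its test. The acinar-like share with LY364947 passed by edgeR on cell counts (4.47).

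Leaving out 1 library gave 175 to 301 genes in beta-like cells after harmine (361 with all), 309 to 457 with GLP1RA, 538 to 651 with LY364947 and 2 to 20 with LY364947 over harmine. In alpha-like cells it gave 427 to 648 after harmine, 535 to 897 with GLP1RA and 667 to 935 with LY364947, in ductal-like cells 13 to 85, 57 to 202 and 86 to 178, and in mesenchymal-like cells 58 to 191, 166 to 318 and 798 to 1192. DMSO replicate 2 moved a count over 1.5 times in each class, with 427 and 535 without it in alpha-like cells, 538 with LY364947 in beta-like cells and 13 after harmine in ductal-like cells. In beta-like cells DMSO replicate 4 and replicates 1, 2 and 4 of harmine did so after harmine (175 without harmine replicate 1), DMSO replicate 3 and replicates 1, 2 and 3 of GLP1RA with GLP1RA (309 without replicate 2), and harmine replicate 3 and replicates 1, 2 and 3 of LY364947 over harmine (2 without replicate 2). In alpha-like cells DMSO replicate 4 and replicate 3 of GLP1RA did too. In ductal-like cells so did DMSO replicate 1, harmine replicates 1, 3 and 4, and every GLP1RA and LY364947 library (57 without replicate 3 of GLP1RA and 86 without replicate 3 of LY364947). In mesenchymal-like cells so did every DMSO library, harmine replicates 1, 2 and 4 (58 without replicate 2), replicates 2, 3 and 4 of GLP1RA and replicates 2 and 4 of LY364947 (798 without replicate 2), with 166 for GLP1RA without DMSO replicate 1.

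Leaving out a donor gave 69 to 255, 101 to 314 and 243 to 443 genes in beta-like cells (0 to 11 with LY364947 over harmine), 225 to 600, 250 to 643 and 406 to 773 in alpha-like cells, 0 to 28, 1 to 78 and 48 to 143 in ductal-like cells, 3 to 127, 12 to 178 and 458 to 914 in mesenchymal-like cells, and 21 to 37, 14 to 46 and 53 to 161 for the difference between classes. Most of the lowest counts came without replicate 2. With GLP1RA over harmine the medians without 1 library ran from −0.19 to 0.0368 for G1/S and −0.29 to 0.19 for G2/M genes in alpha-like cells, and from −0.0603 to 0.17 and −0.19 to 0.30 in beta-like cells, on both sides of 0. The difference in the ductal-like share with an MKI67 or TOP2A UMI ran from −0.918 to 2.45 points after harmine and −0.524 to 3.85 with GLP1RA, both negative without replicate 4. The alpha-like share with LY364947 ran from −1.10 to 2.29 (negative without replicate 3) and the beta-like share from −5.98 to 0.0858 (positive without replicate 4). Medians against DMSO kept their call and direction without any library.

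Of 197 named gene results, 126 kept their call and 193 their direction in every alternative, and 156 and 196 when no library was left out. Doublets kept ended 16 calls, marker classes 21, no filter on low counts 13, stricter filters 6, RLE scaling 1 and wider names 1. The block added 12 and DESeq2 10. INS, which had passed nowhere, reversed in alpha-like cells after harmine (−0.0068 with marker classes, −0.30 to 0.56 without 1 library). In beta-like cells it ran from −0.39 to 0.19 after harmine, −0.45 to 0.20 with GLP1RA and −0.65 to 0.0272 with LY364947, and was positive without DMSO replicate 2 or, for the first 2 treatments, replicate 3 of the treatment. The depth limits the shares of beta-like and mast-like cells, of which thinning left out up to 38.8% and 40.8%, and the smallest p of 4 against 4 libraries, 0.0286, cannot pass over 36 tests unless at least 21 of them reach it, so that this test could hardly pass.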

Other observations

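In mesenchymal-like cells p53 targets rose in 2 of 20 cases after harmine, 7 with GLP1RA and 10 with LY364947 (CDKN1A, BBC3, SESN1, FAS, GDF15, ZMAT3, TNFRSF10B, FDXR, CCNG1 and EDA2R), and with the donor block in 16, 18 and 16. With LY364947, TGF-beta and SMAD targets fell there in 12 of 28 cases, among them COL1A1, COL1A2, FN1, CCN2 and TGFBI, and 1 rose, ID1. In ductal-like cells 9 of 28 fell, among them SMAD7, FN1 and LTBP2. Of the DYRK and CLK kinases with NFAT genes in mesenchymal-like cells with LY364947, 4 of 15 rose (DYRK1B, DYRK3, CLK1 and CLK3) and 1 fell, NFATC1.

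Beta cell identity genes also passed outside the endocrine classes, 3, 7 and 6 of 26 up in ductal-like cells and 2, 7 and 7 of 27 in mesenchymal-like cells after harmine, with GLP1RA and with LY364947. With LY364947, acinar genes rose in 3 of 13 cases in ductal-like cells and 7 of 13 in mesenchymal-like cells. No camera test was run on the lists of these classes.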
